A study of Mus musculus with 2 samples.

How the data were processed

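Immune cells were isolated from mouse livers by collagenase IV digestion, sorted and profiled with the 10x Genomics Chromium droplet system, which tags each captured transcript with a cell barcode and a unique molecular identifier (UMI) so that copies made by PCR are counted as 1 molecule. The labels name 2 samples, 1 control and 1 Rcrin knockout, both 8 weeks old. The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization, as seen from their values. Per the submitters' processing notes, Cell Ranger 2.1.1, STAR, Seurat 2.3.4 and the mm10 assembly were used; which of these made the matrix is not given in the sources used here. Per the file headers, the matrix was written by software version 3.0.0, which is not the Cell Ranger version in those notes. The lowest total of a deposited barcode was 502 UMI; the criterion for calling cells is not given in the sources used here, and free RNA was not measured in empty droplets.

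The matrix, gene list and barcode list of the control sample were each identical byte for byte to those of the knockout sample. The 2 samples therefore held 1 matrix, and all of its barcodes ended in the same suffix, 1. No cell was assigned to a genotype, and no comparison of control with knockout was made. All values describe this matrix as 1 sample. With 1 sample there is no replicate error, no test and no p-value. Shares of cells are given with exact Clopper-Pearson 95% intervals, counts per 1000000 UMI (CPM) with exact Poisson 95% intervals, and ratios of CPM with the exact conditional interval of 2 Poisson counts. These intervals cover counting error only and not the variation between animals. Those of CPM and of ratios treat UMI as independent, so they also leave out the variation between cells of a class.

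Counts were analysed in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9. Barcodes with at least 500 UMI, at least 200 genes and at most 10% mitochondrial UMI were kept. Of 11192 barcodes, 56 had under 200 genes and 778 exceeded the mitochondrial limit, which left 10366. Scrublet called 382 of these (3.69%) doublets, which were removed, and 9984 cells with 60426460 UMI remained. Counts were scaled to 10000 UMI per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with a fixed seed gave 27 clusters, numbered by size.

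Clusters were named from 28 fixed marker lists with 262 genes. A cluster took the class with the highest mean log2 fold over the other cells, provided at least 3 of its markers were each found in at least 25% of the cluster's cells and that fold was at least 1. Clusters with markers of 2 classes (at least 70% of the markers of another class detected, at a fold of at least 0.5 of the highest), without enough markers, or with a median UMI under 1/3 of the sample's and no own marker among the 10 leading genes stayed unnamed. T cell subtypes were merged into 1 class, as were the conventional dendritic subtypes. For each class, UMI were summed over its cells and expressed as CPM. For 21 gene lists with 268 genes, the mean CPM of the members was compared over the 13 classes with at least 30 cells. The median log2 fold of each list in its highest class over all other kept cells, with a pseudocount of 1 CPM, was placed among 10000 random lists of the same size matched on mean expression, each taken in its own class of highest mean CPM. This choice of class was added after the data were seen. With random lists taken in the class of the tested list, as first done, several percentiles differed. They were 98.9 in place of 62.1 for the inflammasome, 99.7 in place of 82.8 for the NF-kB and 99.97 in place of 81.7 for the oxidative phosphorylation list. For the iron and haem list it was 85.5 in place of 15.3, and for the platelet list 44.6 in place of 4.13. For the interferon, T cell activation and inflammatory lists they were 0.84, 12.6 and 7.7 in place of 17.8, 2.64 and 2.99. Of the list genes, 64 were also cell type markers. Because classes were built from the same counts, a level of a marker gene in its class is no independent evidence for that class.

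Genes named in the text are the 5 genes with the highest fold per class among those found in at least 25% of its cells, and the 3 members of each list with the highest CPM in any class, with the highest and the next class. Any other gene named, including those of single clusters, was chosen after its values were seen. The filters, clustering settings, marker and gene lists, rule for the genes named and alternative settings, except the haemoglobin alternative and the basophil-like levels under a higher UMI limit, were fixed before the data were examined. The scoring rule for cluster names, the merging of subtypes, the minimum of 30 cells for ranking and the use of the list medians in place of a comparison of genotypes were set afterwards. An earlier exploratory clustering with approximate neighbours in the doublet caller preceded the reported one, which uses exact neighbours.

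Of the 31053 gene identifiers, 31011 (99.9%) matched GENCODE M21, whose GRCm38 coordinates are given, counted from 1. GRCm38 is the assembly that mm10 denotes. No gene with the symbol Rcrin was found in the matrix or in the symbol tables used, so no value of the targeted gene is given.

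The procedure was tested on simulated data. Each simulated cell was drawn from the summed profile of its own cluster at its own UMI total. Cells of a cluster thus varied by counting error only, which makes clusters easy to find again. These checks cover the running of the procedure. They do not show that clusters, names or intervals hold for the real cells. In 9984 simulated cells over 31053 genes, the clusters found again had an adjusted Rand index of 0.999 with the true ones, and 99.1% of cells of named classes received the same name. Of 400 planted doublets, 82.0% were called, with 0.170% of single cells called in error. Over 5432 genes with 200 planted 2-fold changes, 95.8% of the 95% ratio intervals held the true ratio. Alternatives covered the mitochondrial and UMI limits, doublets, clustering resolution, number of variable genes, seed, the CPM total, thinning to 1000 UMI per cell, the pseudocount and the mean in place of the median.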

Results

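Liver immune cells of 8-week-old mice were profiled by single-cell RNA sequencing, in mice labelled WT, described as floxed, and in mice labelled Rcrin KO, described as a conditional knockout. The design asks which immune classes and genes differ between these genotypes. The files of both samples were identical, so the comparison of genotypes was not made and the cells are described as 1 sample of unknown genotype. The matrix held 67037274 UMI over 11192 barcodes and 31053 genes, of which 10885 had no UMI. Barcodes held from 502 to 93990 UMI, with a median of 4212.5 UMI, 1678 genes and 5.28% mitochondrial UMI. After filtering, 9984 cells with a median of 4247.5 UMI remained.

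B-like and T-like cells were the most abundant classes of the liver suspension. B-like cells made up 29.9% of the kept cells (2981 cells; 95% interval 29.0 to 30.8%) and T-like cells 23.1% (2309 cells; 22.3 to 24.0%). Neutrophil-like cells followed with 9.0% (899 cells; 8.45 to 9.58%), liver sinusoidal endothelial-like cells, which line the hepatic capillaries, with 8.05% (804 cells; 7.53 to 8.60%) and NK-like cells with 5.94% (593 cells; 5.48 to 6.42%). Kupffer-like cells, the resident macrophages of the liver, made up 5.17% (516 cells; 4.74 to 5.62%), of which 133 formed a cluster with a median of 1285 UMI. Classical monocyte-like cells made up 4.55% (454 cells), nonclassical monocyte-like cells 2.74% (274 cells), plasmacytoid dendritic-like cells 2.57% (257 cells) and ILC1-like cells, innate lymphocytes resident in tissue, 2.33% (233 cells). Conventional dendritic-like cells at 0.861% (86 cells), plasma-like cells at 0.751% (75 cells) and basophil-like cells at 0.441% (44 cells) were rare. The conventional dendritic-like cluster took its name from the markers of the subtype cDC1, and no cluster was named for the other subtype. The basophil-like class was named by a list for basophils or mast cells. The classical monocyte-like class was named by a list for classical monocytes and monocyte-derived macrophages. Hepatocyte-like and cholangiocyte-like cells numbered 14 and 12. In all, T-like, NK-like and ILC1-like cells summed to 31.4%, B-like and plasma-like cells to 30.6%, both monocyte classes to 7.29% and the named non-immune classes to 8.31%. The 3 clusters that stayed unnamed held 433 cells (4.34%), 193 of them with markers of both Kupffer and endothelial cells. The sort and the loss of cells during digestion can set these shares. With at most 5% mitochondrial UMI, 4970 cells remained, the T-like share was 27.6%, above the B-like share of 12.0%, and the NK-like, neutrophil-like, classical monocyte-like, endothelial-like, ILC1-like, Kupffer-like, plasma-like, plasmacytoid dendritic-like and basophil-like shares were 9.42, 7.93, 7.65, 5.45, 3.88, 2.86, 1.39, 1.25 and 0.805%. The conventional dendritic-like share moved with filters, doublets, clustering resolution, variable genes and seed, from 0% at resolution 0.5, where no ILC1-like cluster was named either, to 2.72% with 4000 variable genes. With another seed, the conventional dendritic-like class held 154 cells and the classical monocyte-like class 379, in place of 86 and 454. With 4000 variable genes they held 272 and 473 cells, so both were larger. Whether cells of the monocyte-like class were named dendritic-like in other settings was not tested. With at least 1000 UMI and 500 genes the basophil-like class held 78 cells (0.794%), and 1.95% of cells were unnamed. The unnamed share was 12.2% with at most 5% mitochondrial UMI. At resolution 2.0 the classical monocyte-like share was 2.73%.

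**Figure D1:**
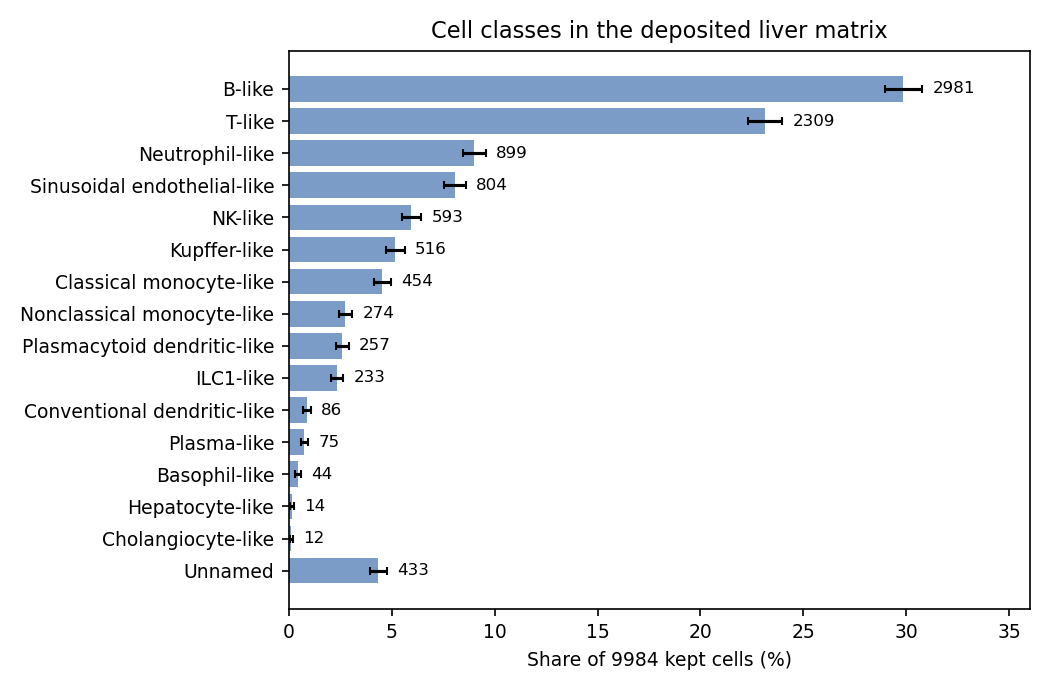
Share of the 9984 kept cells in each class, in percent, with exact 95% binomial intervals (counting error only) and the number of cells beside each bar. B-like cells (29.9%) and T-like cells (23.1%) are the 2 most abundant classes, and 433 cells are unnamed.

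The 5 leading genes of the classes by fold held known cell type genes and, for some classes, genes with no assigned function such as AC163354.1 and A530099J19Rik. Ebf1 and Pax5, transcription factors of the B lineage, led the B-like class at 2013 and 568 counts per 1000000 UMI (CPM), with Fcmr, Ms4a1 and Ighd. Cd3e and Cd3d, parts of the T cell receptor complex, led the T-like class at 499 and 825 CPM, with Bcl11b, Themis and Lef1. Neutrophil-like cells were led by Retnlg, S100a9, S100a8, Lcn2 and Stfa2l1, and endothelial-like cells by Jam2, F8, Timp3, Ramp2 and Gja1. NK-like cells were led by Klra4 (655 CPM), Klra8, Cma1, Klra3 and Adamts14, and ILC1-like cells by Cd200r2, Zmat4, Klrb1b (525 CPM), AC163354.1 and Klra5. Kupffer-like cells were led by Fabp7 (471 CPM), C1qc, C1qa, C1qb and Marco (809 CPM). Classical monocyte-like cells were led by F13a1 (624 CPM), Vcan, Fn1, Stxbp6 and Mcub, and nonclassical monocyte-like cells by Ace (676 CPM), Eno3, Krt80, Ly6i and Dusp16. Plasmacytoid dendritic-like cells were led by Siglech (2498 CPM), Gm21762, Klk1, Cox6a2 and Ccr9, and conventional dendritic-like cells by Xcr1 (422 CPM), A530099J19Rik, Sept3, Gcsam and Ttc39a. Plasma-like cells were led by the immunoglobulin genes Jchain (27876 CPM), Ighg2c, Ighg2b, Igha and Iglv1, and basophil-like cells by Mcpt8 (2454 CPM), Cyp11a1, Cpa3, Cd200r3 and Ms4a2. Fabp1, Bhmt, Fbp1, Car3 and Gsta3 led the hepatocyte-like cells, and Clu, Spp1, Tm4sf4, Krt8 and Sorbs2 the cholangiocyte-like cells. These genes identify the classes and are not a result of their own.

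The T-like class held 7 clusters with different CD4, CD8, cytotoxic and naive genes. Cluster 6 (587 cells) had Cd8b1 at 863 CPM, Gzmk at 283 CPM and Gzmb at 925 CPM, whereas cluster 7 (454 cells) had Cd8b1 at 513 CPM with Lef1 at 581 CPM and the lymph node homing receptor Ccr7 at 643 CPM. Cluster 11 (347 cells) had Lef1 at 911 CPM and Cd4 at 160.0 CPM. Cluster 14 (252 cells) had Cd4 at 245 CPM, the inhibitory receptor Ctla4 at 949 CPM and Foxp3, the transcription factor of regulatory T cells, at 74.8 CPM. Cluster 9 (412 cells) had Zbtb16, the transcription factor of innate-like T cells, at 177 CPM and Cxcr6, a receptor for liver residence, at 509 CPM. Cluster 16 (218 cells) had Cd8a at 484 CPM but Cd8b1 at 81.0 CPM, with Ikzf2 at 983 CPM and Gzmb at 2717 CPM. Cluster 25 (39 cells) had the gamma-delta receptor gene Trdc at 724 CPM and the cytokine Il17a at 882 CPM. Gamma receptor genes were also among the 10 leading genes of cluster 9 (Tcrg-C1 and Tcrg-C4) and of cluster 16 (Tcrg-C2 and Trgv2). The borders of these clusters were set by the same counts.

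**Figure D2:**
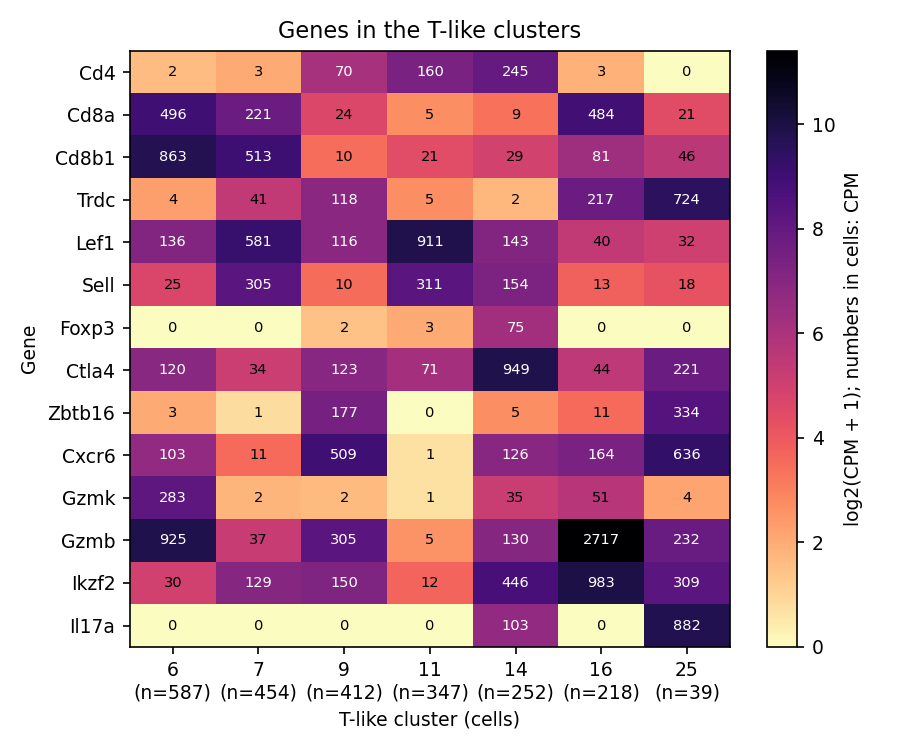
Level of 14 genes (rows) in the 7 T-like clusters (columns, with the number of cells), as counts per 1000000 UMI (CPM) printed in each cell and colour on a log2 scale after adding 1. Lef1 peaks in cluster 11 at 911 CPM, Gzmb in cluster 16 at 2717 CPM and Il17a in cluster 25 at 882 CPM.

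Among whole classes, cytotoxic effector genes were highest in NK-like cells and next in ILC1-like cells. The 12 members had a mean of 3524 CPM in NK-like and 2130 CPM in ILC1-like cells; 6 members peaked in the first and 5 in the second class, and all 12 lay above the level in the other cells of the matrix in NK-like cells (median log2 fold 3.02, percentile 100 of matched random lists that also took their own highest class). The chemokine Ccl5 was at 23553 CPM in NK-like cells, 1.94-fold (1.91 to 1.98) its level in ILC1-like cells. The list was not ranked over single T-like clusters, and Ccl5 was among the 10 leading genes of T-like cluster 6. Gzma, a granzyme, was 1.69-fold (1.65 to 1.73) higher in NK-like than in ILC1-like cells, whereas Gzmb, among whole classes, was highest in ILC1-like cells at 2586 CPM (2492 to 2682); T-like cluster 16 was at 2717 CPM. Eomes, a transcription factor of NK cells, was at 329 CPM (307 to 352) in NK-like and 11.6 CPM (6.2 to 19.9) in ILC1-like cells. Prf1, which encodes the pore-forming protein perforin, was at 1386 and 262 CPM, and the chemokine Xcl1 was at 141 and 1596 CPM. Eomes, Gzma, Prf1 and Xcl1 are markers of these classes, as is the list member Klrk1. The naive lymphocyte list was highest in T-like cells at 404 CPM and next in B-like cells at 389 CPM, with 4 of 9 members peaking in T-like cells (median log2 fold 1.59, percentile 99.9). Lef1, Tcf7, Il7r and Ccr7 of this list are also T cell markers used for naming. Ccr7 was 2.96-fold (2.84 to 3.09) higher in B-like than in T-like cells, Satb1 1.07-fold (1.05 to 1.10), and Klf2 was highest in Kupffer-like cells at 1415 CPM, an order over endothelial-like cells that turned when cells were thinned to 1000 UMI. The T cell activation and exhaustion list was highest in basophil-like cells at 159 CPM, with 1 of 12 members peaking there and 4 in T-like cells (median log2 fold -1.79, percentile 2.64). With random lists taken in basophil-like cells, the percentile was 12.6. The member that peaked in basophil-like cells, the early activation antigen Cd69, gave 88.0% of the list's CPM. Icos peaked in T-like cells at 321 CPM and Cd44 in neutrophil-like cells at 1152 CPM. Cd44 was almost equal in neutrophil-like and nonclassical monocyte-like cells, with the order just turned, under a reduced CPM total. That total left out haemoglobin, hepatocyte, mitochondrial and ribosomal protein genes.

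B-like cells fell into 2 clusters that differed in immunoglobulin heavy chain genes. Ighd, the IgD constant region, was at 897 CPM (877 to 917) in cluster 1 (2377 cells) and 382 CPM (356 to 409.5) in cluster 4 (604 cells). Ighm, the IgM constant region, went the other way, at 3537 CPM (3497 to 3577) and 7794 CPM (7676 to 7914). Fcer2a, the gene of the low-affinity IgE receptor CD23, was at 298 CPM in cluster 1 and 133 CPM in cluster 4. Among the named classes, the cell cycle list was highest in plasma-like cells at 147 CPM, where 10 of 18 members peaked (median log2 fold 1.24, percentile 99.98). An unnamed cluster of 177 cells, left out of this ranking, had Mki67 at 878 CPM and Top2a at 975 CPM, against 490.2 and 223 CPM in plasma-like cells. Mki67, a proliferation marker, was 10.5-fold (9.14 to 12.0) higher in plasma-like cells than in the next named class, Kupffer-like cells. Hmgb2 peaked in neutrophil-like cells at 1609 CPM and Tubb5 in endothelial-like cells at 308 CPM. The oxidative phosphorylation list was also highest in plasma-like cells at 285 CPM, with classical monocyte-like cells close at 269 CPM and 3 of 15 members peaking in plasma-like and 4 in classical monocyte-like cells (median log2 fold 0.16, percentile 81.7). Ndufa4 peaked in plasma-like cells (805 CPM), Cox5a in Kupffer-like cells (858 CPM) and Cox4i1 in classical monocyte-like cells (1048 CPM).

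Kupffer-like cells were highest for genes of efferocytosis, the uptake of dying cells, and for lipid handling. Of the 15 efferocytosis and complement genes, 10 peaked in Kupffer-like cells and the other 5 in endothelial-like cells, with means of 1386 and 427 CPM (median log2 fold in Kupffer-like cells 3.75, percentile 100). The mean log2 fold was 2.11. Timd4, C1qa, C1qb, C1qc, Vsig4, Marco and Cd163 are also markers used to name the Kupffer-like class, so the percentile is no independent result. C1qb, C1qa and C1qc, the chains of complement C1q, were at 5143, 5063 and 4113 CPM in Kupffer-like cells. Of the 15 lipid handling genes, 7 peaked in Kupffer-like cells, with a mean of 1435 CPM against 529 CPM in endothelial-like cells (median log2 fold 1.57, percentile 100). The apolipoprotein gene Apoe was at 14428 CPM in Kupffer-like cells, 3.77-fold (3.72 to 3.83) its level in endothelial-like cells, and gave 67.0% of the list's CPM. Apoc1 was at 2748 CPM in Kupffer-like cells, and Fabp4 peaked in endothelial-like cells at 1608 CPM. The iron and haem list had its highest mean in neutrophil-like cells at 2334 CPM, but 8 of 13 members peaked in Kupffer-like cells, whose mean was 1433 CPM. The ferritin heavy chain gene Fth1 gave 72.7% of the list's CPM in neutrophil-like cells, where it was at 22049 CPM (median log2 fold of the list -0.75, percentile 15.3). Slc40a1, the iron exporter ferroportin, was at 2151 CPM in Kupffer-like cells, 7.77-fold (7.39 to 8.16) higher than in endothelial-like cells. Slc40a1 is also a marker used to name the Kupffer-like class, so its peak there is no independent result. Ftl1 was at 7378 CPM in basophil-like and 7061 CPM in Kupffer-like cells, a ratio of 1.04 whose interval (0.995 to 1.10) includes no difference. The resolution and repair list had its highest mean in endothelial-like cells at 189.6 CPM, but 5 of 14 members peaked in classical monocyte-like and 4 in Kupffer-like cells. In endothelial-like cells 1 member, the mannose receptor gene Mrc1, peaked at 2289 CPM and gave 86.2% of the CPM (median log2 fold -1.71, percentile 0.170). Igf1 peaked in Kupffer-like cells at 643 CPM and Chil3 in classical monocyte-like cells at 402 CPM.

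Among the ranked classes, neutrophil-like cells had the highest level of interleukin 1 beta transcripts, and they formed 2 clusters with different granule genes. Il1b was at 8487 CPM (8376 to 8599.5), 5.47-fold (5.24 to 5.71) its level in nonclassical monocyte-like cells. The 73 cells of cluster 22 had the secondary granule genes Ngp at 22605 CPM, Camp at 17203 CPM and Ltf at 7126 CPM, with Il1b at 496 CPM. The 826 cells of cluster 2 had Ngp at 62.0 CPM and Camp at 3.75 CPM, with Il1b at 10277 CPM and the chemokine Cxcl2 at 15599 CPM. The dissociation stress list, genes induced by tissue digestion, had a mean of 1285 CPM in neutrophil-like cells, next after basophil-like cells. Transcripts induced by digestion were not separated here. Neutrophil granule genes had a mean of 14987 CPM in neutrophil-like cells, with 9 of 12 members peaking there (median log2 fold 8.53, percentile 100). The mean log2 fold was 5.54, and the median was 7.09 with a pseudocount of 10 CPM. S100a8, S100a9, Retnlg, Mmp9, Camp, Ngp, Ltf and Mmp8 are also markers used to name this class, so the percentile is no independent result. S100a9 and S100a8, the subunits of calprotectin, were at 95443 and 60740.1 CPM, and Retnlg was at 9357 CPM. The inflammasome list was also highest in this class at 850.1 CPM, but Il1b gave 83.2% of that and was the 1 member of 12 that peaked there, against 4 in Kupffer-like cells. Its median log2 fold was -0.04 and its mean log2 fold 0.11, with the median at percentile 62.1. Nlrp3, an inflammasome sensor, peaked in basophil-like cells at 2246 CPM and Pycard, an inflammasome adaptor, in plasma-like cells at 1523 CPM. Glycolysis and hypoxia genes were highest in neutrophil-like cells at 241 CPM, with 4 of 14 members peaking there (median log2 fold 0.78, percentile 99.6). Gapdh was at 1100.5 CPM, 1.31-fold (1.25 to 1.38) its level in classical monocyte-like cells, and Pkm was at 679 CPM. Ldha did not differ detectably between its highest classes, basophil-like and conventional dendritic-like cells (ratio 1.03, interval 0.830 to 1.27), and their order turned with 3 alternative settings.

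Class II antigen presentation genes were highest in conventional dendritic-like cells, and class I genes had no single class in which most of them peaked. Of 10 class II genes, 7 peaked in conventional dendritic-like cells and 2 in B-like cells, with means of 3355 and 2092 CPM (median log2 fold 2.24, percentile 99.99). Cd74, the invariant chain, was at 13118 CPM in conventional dendritic-like cells, 1.21-fold (1.19 to 1.23) its level in B-like cells, while H2-Ab1 was 2.44-fold (2.38 to 2.50) and H2-Aa 1.94-fold (1.88 to 1.99) higher. The conventional dendritic-like cluster had all 10 markers of the cross-presenting subtype cDC1. Cd209a, a marker of the other subtype, was at 162 CPM in the classical monocyte-like cluster and 19.9 CPM in the dendritic-like cluster, and whether the monocyte-like cells with Cd209a are dendritic cells was not tested. Of 11 class I genes, 4 (Tap1, Tap2, Psmb8 and Psmb9) peaked in conventional dendritic-like cells, 3 in ILC1-like cells and 2 in nonclassical monocyte-like cells, with means of 586, 1049 and 1016 CPM. The median log2 fold in ILC1-like cells, the class with the highest mean, was 0.62 (percentile 98.7). H2-K1 was at 3943 CPM in ILC1-like cells, and B2m and H2-D1 were at 4089 and 3455 CPM in nonclassical monocyte-like cells. The interferon response list was highest in plasmacytoid dendritic-like cells at 249 CPM and next in endothelial-like cells at 151 CPM, with 2 of 21 members peaking in the first, 4 in the second and 5 in Kupffer-like cells (median log2 fold -0.71, percentile 17.8). With random lists taken in plasmacytoid dendritic-like cells, the percentile was 0.84. Bst2, also a marker of the plasmacytoid class, was at 4144 CPM there and gave 79.3% of the list's CPM. Irf7 peaked in Kupffer-like cells at 579.6 CPM and Isg15 in neutrophil-like cells at 558 CPM.

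The 44 basophil-like cells had the highest levels of several chemokine and immediate early genes. Ccl4 was at 37763 CPM (36974 to 38564), 5.86-fold (5.71 to 6.02) its level in plasmacytoid dendritic-like cells, and Ccl3 was at 22980.3 CPM, 19.1-fold (18.0 to 20.3) its level in ILC1-like cells. The inflammatory list had a mean of 4375 CPM in basophil-like and 1472 CPM in NK-like cells, with 5 of 18 members, Ccl3, Ccl4, Il6, Ptgs2 and Tnf, peaking in basophil-like cells and 5 others in Kupffer-like cells. Its median log2 fold there was -1.37 (percentile 2.99), whereas its mean log2 fold was 0.47, so the high mean rested on a few members. The NF-kB feedback list had its highest mean in basophil-like cells at 1097 CPM, but 7 of 13 members peaked elsewhere (median log2 fold 0.18, percentile 82.8). Zfp36, Nfkbia and Nfkbiz, at 4656, 3516 and 3468 CPM, gave 81.6% of the list's CPM, and the median member was at 126 CPM there against 193 CPM in nonclassical and 175 CPM in classical monocyte-like cells. The dissociation stress list, genes induced by tissue digestion, was also highest in this class at 2519 CPM, with 8 of 17 members peaking there (median log2 fold 1.69, percentile 100). Egr1 was at 8445 CPM, Junb at 7625 CPM and Ier3 at 7153 CPM. When cells were thinned to 1000 UMI, Junb was almost equal in basophil-like and neutrophil-like cells, with the order just turned. The lowest mean of the stress list, 168 CPM, was in plasma-like cells. These levels rest on 230676 UMI, and transcripts induced by digestion were not separated from those present in the liver. With at least 1000 UMI and 500 genes, the class took in 34 cells that were otherwise unnamed beside the same 44, and Ccl3 and Egr1 were at 6964 and 2756 CPM in these 78 cells.

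**Figure D3:**
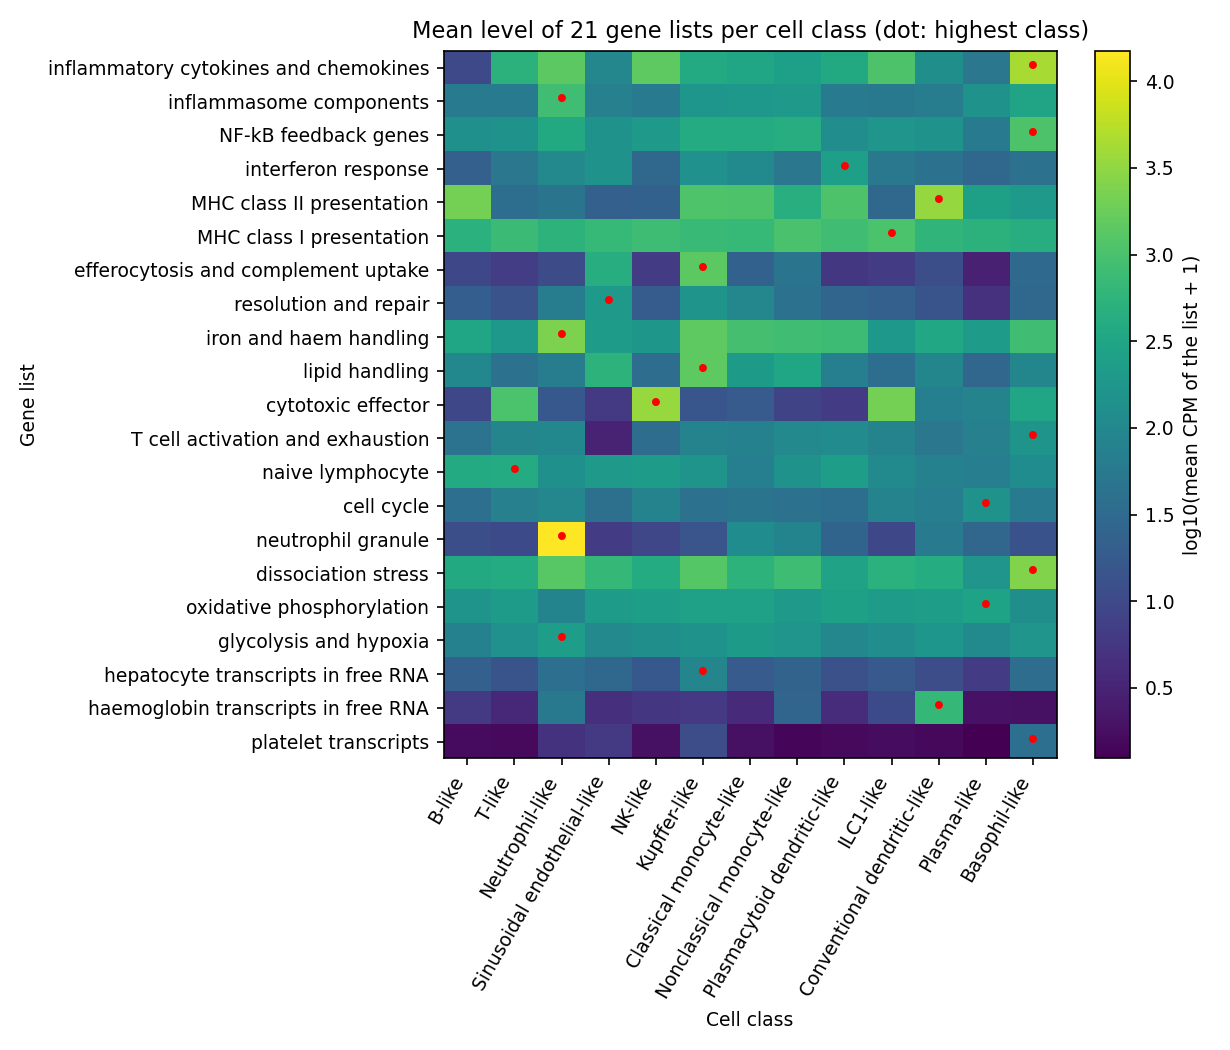
Mean level of the members of each of the 21 gene lists (rows) in the 13 classes with at least 30 cells (columns), in CPM on a log scale. The neutrophil granule list reaches 14987 CPM in neutrophil-like cells and the cytotoxic list 3524 CPM in NK-like cells.

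Transcripts of hepatocyte genes were found in every ranked class. Alb, the albumin gene, had a UMI in 24.7% of B-like, 22.3% of T-like, 26.3% of neutrophil-like and 20.4% of NK-like cells, and in 50.7% of endothelial-like and 74.0% of Kupffer-like cells, whose median depths were 3239, 4868, 2563, 3900, 7323.5 and 13167.5 UMI. With each cell thinned to 1000 UMI, which kept 2971, 2296, 893, 592, 804 and 462 cells of these classes, these shares were 9.86, 6.53, 11.8, 7.94, 10.7 and 19.0%. Among the ranked classes, the hepatocyte list was highest in Kupffer-like cells at 89.5 CPM, with 10 of 13 members peaking there (median log2 fold 0.85, percentile 98.9). The 14 hepatocyte-like and 12 cholangiocyte-like cells were too few to be ranked. The list made up 4.97% and 0.929% of their UMI, against 0.116% in Kupffer-like cells. Trf, the transferrin gene, was at 662 CPM and gave 56.9% of the list's CPM, with Alb at 231 CPM and Apoa2 at 39.3 CPM in that class. Trf was 3.18-fold (2.40 to 4.32) over its next class, basophil-like cells, where it was at 208 CPM. Alb was 1.64-fold and Apoa2 1.57-fold over their next classes, so Trf did not follow them. Whether these transcripts, Trf above all, came from hepatocytes was not tested. The haemoglobin list was highest in conventional dendritic-like cells at 651 CPM, with all 5 members peaking there (median log2 fold 6.69, percentile 100) and Hbb-bs, Hba-a1 and Hba-a2 at 1174, 990.0 and 786 CPM. In this class 2 cells held an Hbb-bs UMI, and 1 of them held 1296, nearly all of the class's Hbb-bs UMI. Without these 2 cells the mean of the list was 0.364 CPM, and the order turned with doublets kept. The platelet list was highest in basophil-like cells at 37.3 CPM through Itga2b (182 CPM), which gave 97.7% of it. Its median log2 fold there was -0.78 (percentile 4.13) and its mean log2 fold 0.10. With random lists taken in basophil-like cells, the percentile was 44.6. Pf4 peaked in Kupffer-like cells at 50.1 CPM and Ppbp in neutrophil-like cells at 3.45 CPM.

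Several of the named genes lie close together in the genome (GRCm38, GENCODE M21, all protein coding). The chemokine genes Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, minus strand), Ccl3 (ENSMUSG00000000982, 83647844 to 83649355, minus strand) and Ccl4 (ENSMUSG00000018930, 83662584 to 83664683, plus strand) share a stretch of chromosome 11. Among whole classes, Ccl5 was nonetheless highest in NK-like and the other 2 in basophil-like cells. S100a8 (ENSMUSG00000056054, 90668978 to 90670035, plus strand) and S100a9 (ENSMUSG00000056071, 90692632 to 90695721, minus strand) are neighbours on chromosome 3 and both peaked in neutrophil-like cells. Il1b (ENSMUSG00000027398) lies on chromosome 2 at 129364570 to 129371139 on the minus strand, Apoe (ENSMUSG00000002985) on chromosome 7 at 19696109 to 19699188 on the minus strand and C1qb (ENSMUSG00000036905) on chromosome 4 at 136880129 to 136886187 on the minus strand. Gzma (ENSMUSG00000023132) lies on chromosome 13 at 113093825 to 113100981 on the minus strand, Slc40a1 (ENSMUSG00000025993) on chromosome 1 at 45908068 to 45926523 on the minus strand and Alb (ENSMUSG00000029368) on chromosome 5 at 90460897 to 90476602 on the plus strand. UMI were counted per gene, so no exon or untranslated region is attached to these values.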

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

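The haemoglobin alternative and the basophil-like levels under a higher UMI limit were chosen after the data were seen; the others were planned. Basophil-like levels rest on 44 cells and 230676 UMI, and all 7 levels recomputed with at least 1000 UMI and 500 genes were lower, with Mcpt8 at 731.5 CPM in place of 2454 CPM, since 34 otherwise unnamed cells joined the class. No paired analysis was possible because both samples held 1 matrix. The alternatives on the minimum number of UMI per gene were not run, since they applied to the comparison of genotypes. Of the class shares, 86 stayed within their interval and 45 moved; no cause was tested beyond what each setting removes. With at most 20% mitochondrial UMI, shares were 0.641% for conventional dendritic-like, 6.37% for Kupffer-like, 9.90% for endothelial-like and 22.1% for T-like cells, with 3.72% unnamed. With at most 5%, which removed 5014 more cells, they were 12.0% for B-like, 27.6% for T-like, 9.42% for NK-like, 7.93% for neutrophil-like, 7.65% for classical monocyte-like, 5.45% for endothelial-like, 4.06% for nonclassical monocyte-like, 3.88% for ILC1-like, 2.86% for Kupffer-like, 2.60% for conventional dendritic-like, 1.39% for plasma-like, 1.25% for plasmacytoid dendritic-like, 0.805% for basophil-like and 0.724% for progenitor-like cells, 0% for cholangiocyte-like cells and 12.2% unnamed. With at least 1000 UMI and 500 genes, they were 24.6% for T-like, 8.62% for endothelial-like, 4.63% for Kupffer-like, 3.76% for classical monocyte-like, 1.52% for conventional dendritic-like and 0.794% for basophil-like cells, with 1.95% unnamed. With doublets kept, they were 8.62% for endothelial-like, 3.97% for classical monocyte-like and 1.35% for conventional dendritic-like cells. At resolution 0.5 no conventional dendritic-like or ILC1-like cluster was named (0%), and shares were 21.1% for T-like, 5.80% for Kupffer-like and 2.42% for progenitor-like cells, with 6.48% unnamed. At resolution 2.0, they were 24.6% for T-like, 2.73% for classical monocyte-like and 0.381% for progenitor-like cells. With 4000 variable genes, conventional dendritic-like cells made up 2.72%, hepatocyte-like cells 0% and unnamed cells 2.56%. Another seed gave 1.54% conventional dendritic-like and 3.80% classical monocyte-like cells. Of the ratios of named genes between their highest and next class, 163 stayed within their interval, 76 moved and 9 turned. The log2 ratio turned for Cd44 (-0.003067) and Ldha (-0.0939) with the reduced CPM total, for Klf2 (-0.0749), Junb (-0.000323) and Ldha (-0.30) after thinning, for Ldha (-0.0769) with at most 20% mitochondrial UMI, and for Hbb-bs (-4.82), Hba-a1 (-4.40) and Hba-a2 (-4.72) with doublets kept; the cause was not tested. Of the list values, 32 stayed within 1 log2 unit, a bound set after the data were seen, 7 moved and 3 turned. With the mean in place of the median, the log2 fold turned for the inflammatory (0.47), inflammasome (0.11) and platelet (0.10) lists and moved for the efferocytosis (2.11) and neutrophil granule (5.54) lists. A pseudocount of 10 CPM gave -0.30 for the inflammatory, -0.32 for the resolution, -0.61 for the T cell activation, 7.09 for the neutrophil granule and 5.58 for the haemoglobin list. Thinning to 1000 UMI lowered the share of cells with an Alb UMI to 9.86% for B-like, 6.53% for T-like, 11.8% for neutrophil-like, 7.94% for NK-like, 19.0% for Kupffer-like and 10.7% for endothelial-like cells. Without the 2 cells with an Hbb-bs UMI, the haemoglobin list in conventional dendritic-like cells was at 0.364 CPM.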

Other observations

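The test of nuclear transcripts for pieces with little cytoplasmic RNA and the test of Xist were chosen after the results they measure had been seen, and so was the control for the comparison of Kupffer-like profiles. A cluster of 177 cells that stayed unnamed was high in cell cycle genes. Its levels of the proliferation genes Mki67 and Top2a were 878 CPM (844 to 913) and 975 CPM (939 to 1011). The T cell gene Cd3e was at 206 CPM, the monocyte gene Ly6c2 at 477 CPM, the B cell gene Cd79a at 88.3 CPM and the progenitor gene Kit at 53.2 CPM in that cluster. These genes were chosen after their values were seen, and whether they lie in separate cells, in doublets or in free RNA was not tested.

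A cluster of 193 cells had markers of both Kupffer and endothelial cells. Its median of 24347 UMI was above that of the larger Kupffer-like cluster (15562) and of the endothelial-like cluster (7323.5), and near their sum of 22885.5. Droplets with 2 cells or attached cell pieces may account for it: 100% of 191 endothelial genes lay within 2-fold of their median ratio of 41.2% to the endothelial-like level. Likewise, 100% of 151 Kupffer genes lay within 2-fold of their median ratio of 59.7% to the larger Kupffer-like cluster. The median doublet score was 0.0856, against 0.0207 in all kept cells. These 193 cells are among the other cells in the folds of the Kupffer-like and endothelial-like classes. Free endothelial RNA is argued against, since the endothelial share of UMI was 20.4 times that of the larger Kupffer-like cluster. No biological explanation was tested, and Dcn, S100a8 and S100a9, 3 of 1841 genes, were over 2-fold above both parent clusters, which the pair alone leaves open.

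The Kupffer-like class held a cluster of 133 cells with a median of 1285 UMI. Shallower cells with the same profile are argued against, since 15.8% of 879 genes were over 2-fold apart from the larger cluster, against 1.15% when that cluster was thinned to the same depth; the bound of 20% written beforehand was not met, so this rests on the control added later. Pieces with little cytoplasmic RNA are argued against, since the nuclear transcripts Malat1 and Neat1, which should rise, were at 0.346 (0.329 to 0.363) and 0.0760 (0.0543 to 0.104) of their level in the larger cluster; a first test, the ratio of mitochondrial shares of 1.07, decided nothing, as cells over 10% had been removed. Pieces without a nucleus stay open, since the same low Malat1 fits them, by a bound written before Malat1 but after low Neat1, Fosb and Btg2 were seen. Low Malat1 was not particular to this cluster. An unnamed cluster of 63 cells, with endothelial markers and a median of 1183 UMI, had Malat1 at 0.143 (0.127 to 0.160) of the larger endothelial-like cluster. Its Neat1 was at 0.221 (0.101 to 0.421). No biological explanation was tested, and Igha, at 5786 CPM there and 14.8 CPM in the larger cluster, could come from plasma cell RNA, which was not tested.

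The single matrix given for both samples could pool animals of both sexes. Of 1221 cells with at least 10000 UMI, 0.246% (3 cells; 0.0507 to 0.716%) held a UMI of Xist, the transcript of the inactive X chromosome in females, which argues against such a pool. A first test on 4 Y-linked genes, found in 91.9% of these cells (90.2 to 93.4%), had not decided it, and the Xist test was chosen after that. A pool of animals of 1 sex, or of both genotypes, stays open.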
